A study of Mus musculus with 2 samples.

How the data were processed

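MicroRNA-seq, which reads short RNAs and counts them on annotated microRNA (miRNA) genes, was run on gastrocnemius, the large calf muscle. The tissue came from adult female mice of the F1 hybrid strain B6CASTF1/J aged 18 to 20 months. The series holds 2 libraries in 1 group, which the labels number as biological replicates 1 and 2. Both libraries carry the same donor entry in the labels but separate tissue sample entries. Nothing in the labels settles whether 2 animals were used, so differences between these libraries may be technical.

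The deposited values are counts of reads per miRNA gene, with no normalization. Per the deposited README, they refer to the mouse assembly mm10 and the GENCODE annotation M21. The aligner, the counting tool and any trimming of adapters are not given in the sources used here. Each deposited count file holds 4 tallies (unmapped, multimapping, no feature and ambiguous reads) followed by 2202 miRNA genes by Ensembl identifier. All 2202 identifiers matched the annotation, from which symbols, coordinates, host genes and hairpin sequences were taken. The 3 count columns carry no header. From their values they hold unstranded, sense and antisense counts, and the sense column was used because its sum over miRNA genes was larger in both libraries. Multimapping reads have a tally of their own and enter no gene count.

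Tallies stayed out of library sizes and tests. Of all reads, 80.7% in replicate 1 and 71.0% in replicate 2 were multimapping, 5.10% and 8.17% were unmapped, and 1.67% and 2.73% fell outside miRNA genes. No read was ambiguous in the sense column. CPM values are counts divided by the library's gene counts and multiplied by 1000000. The gene counts were 865419 in replicate 1 and 2177048 in replicate 2. A gene with 0 counts could still lie at up to 3 counts, or 3.47 CPM in replicate 1 and 1.38 CPM in replicate 2. These floors and all intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

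The 305 genes with a mean of at least 10 counts were compared. Agreement was measured as Pearson's r and Spearman's rho across genes of log2(CPM + 1), with 1000 bootstrap draws of genes; genes are not independent replicates, so no p was taken. Each gene was compared between the libraries by a two-sided exact conditional binomial test against the library totals, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a ratio of at least 2. This test compares the 2 libraries and their counting error, and says nothing of animals or conditions. A ratio against a count of 0 was taken against the floor of 3 counts. The spread beyond counting error was estimated as the biological coefficient of variation by edgeR 4.0.16 in R 4.3.3 from an intercept-only fit, with 100 bootstrap fits. The share of counts in each of 19 gene lists has an exact Clopper-Pearson interval. The median log2 ratio of a list was placed among 10000 random lists of the same size, in which each member was drawn from the 20 genes nearest in mean CPM. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

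The tests, the lists and the rule for naming genes were fixed before the data were examined. The rule takes the 25 genes with the highest mean CPM, up to 4 members each of the lists striated muscle, slow fibre, erythroid, leukocyte, endothelial, fibroblast, smooth muscle and liver, and the 10 called genes with the largest absolute log2 ratio. The other lists were Mir486, epithelial, neural, pancreas, let-7, senescence and fibrosis, Hox clusters, the Mir17 to Mir92 cluster, the Mir30 family, the imprinted Dlk1-Dio3 cluster and the Sfmbt2 cluster. Older symbols in the annotation were matched to list members by identifier (Mir142 for Mir142a, Mir146 for Mir146a, Mir486 and Mir3107 for Mir486a and Mir486b).

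On simulated Poisson counts with the real totals, the binomial test called 88.6% of genes changed 3-fold, 93.7% of genes changed 8-fold and 0 of 212 unchanged genes, over 319 tested genes. These counts hold no spread beyond counting error, so they cannot show how many calls such spread would give. On simulated normal values, independent between genes and unrelated to level, 6 of 100 random lists fell outside the central 95% of their matched draws. That check does not cover a trend of the ratios with level or list members that move together. Simulated coefficients of 0.2, 0.5 and 0.8 were estimated as 0.187, 0.494 and 0.781 over 305 genes. The alternatives tried were the unstranded column, no filter or a mean of at least 100 counts, a pseudocount of 0.5 CPM, no ratio threshold, TMM and DESeq2 1.42.0 size factors, genes with a copy number left out, the top gene left out of the totals, and each library left out in turn. No genome sequence was used, and the reads themselves, the signal tracks and the alignments were not analysed here.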

Results

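Short RNAs of gastrocnemius, a mixed calf muscle of mostly fast fibres, were sequenced from aged female B6CASTF1/J mice as 2 libraries of a single group. The files count 6888732 reads for replicate 1 and 12001270 for replicate 2, of which 865419 (12.6%) and 2177048 (18.1%) were assigned to miRNA genes on the sense strand. Replicate 2 therefore held 2.52 times as many gene counts. Multimapping reads outnumbered gene counts in both libraries, by 6.42 to 1 in replicate 1 and 3.91 to 1 in replicate 2. With 1 group, the design asks which miRNAs this muscle holds and how closely its replicates agree. Errors are SD over both libraries (n = 2) unless a counting interval is named.

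**Figure D1:**
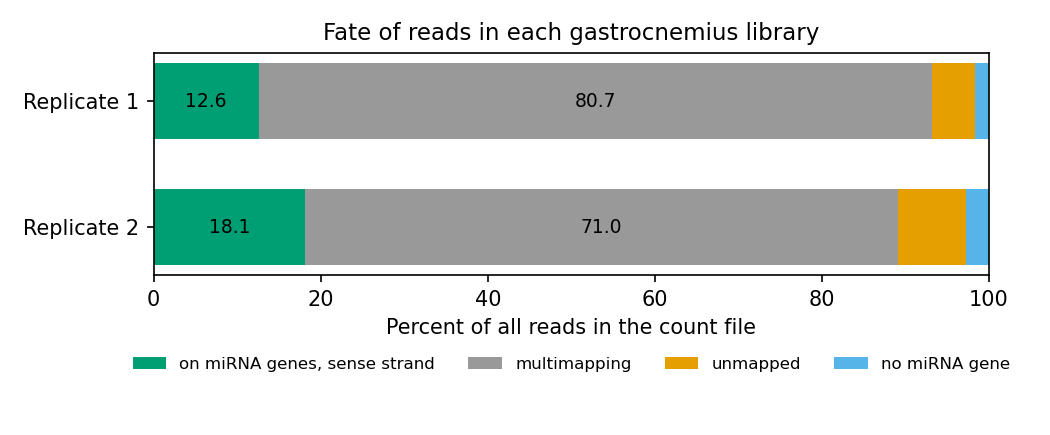
Horizontal bars show the percent of all reads in each library's count file by fate: on miRNA genes in the sense direction, multimapping, unmapped, or on no miRNA gene. Multimapping reads took 80.7% of replicate 1 and 71.0% of replicate 2, against 12.6% and 18.1% on miRNA genes.

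Mir378a led the gene counts, which leave out multimapping reads, in both libraries, and Mir206 and Mir22 followed by mean CPM. They followed it in replicate 2 but not in replicate 1, where Mir143 stood next at 67550 CPM. Mir378a, which lies in an intron of the metabolic coactivator gene Ppargc1b (ENSMUSG00000105200.1, mm10 chromosome 18, 61397835 to 61397900, minus strand), reached 152675 ± 40587 CPM, or 15.3% ± 4.06 of all gene counts. Mir206, a miRNA of skeletal muscle (ENSMUSG00000065559.1, chromosome 1, 20679010 to 20679082, plus strand, in an exon of the long noncoding RNA Gm28653), stood at 71810 ± 44437 CPM, with 40388 in replicate 1 and 103232 in replicate 2. Mir22 (ENSMUSG00000065529.1, chromosome 11, 75463716 to 75463810, plus strand, in an annotated exon of Tlcd2) stood at 71720 ± 52389 CPM, with 34676 and 108765. The let-7 genes Mirlet7i and Mirlet7g followed at 54697 ± 3713 and 54599 ± 1760 CPM, then Mir143 of smooth muscle at 51346 ± 22915 CPM and Mir126a of endothelium at 50123 ± 4023 CPM. Mir378a and Mir126a each face an annotated miRNA gene on the other strand, so the unstranded column, where their reads are ambiguous, gives them 0 and 0.869 CPM.

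Mir23a (40390 ± 493 CPM), Mir23b (38061 ± 2394 CPM) and Mir99a (34534 ± 6657 CPM) completed the 10 highest genes. Next came Mirlet7b, Mirlet7d, Mir26b, Mir30a, Mir10b, Mir29a, Mir139, Mir100, Mir149 and Mir21a, which ranged from 32318 ± 6549 CPM for Mirlet7b to 10580 ± 7564 CPM for Mir21a. Mir30d, Mir191, Mir744, Mir30e and Mir196b closed the 25 highest genes, and Mir196b stood at 7899 ± 1743 CPM. Of the 25 genes, 10 lie in introns of protein-coding genes and 4 lie outside any other annotated gene. The counts were concentrated in few genes. The top 5 genes held 42.6% ± 2.33 of gene counts, the top 10 held 62.9% ± 2.74 and the top 20 held 82.9% ± 0.0749. The genes that together held 90% of counts numbered 29 in replicate 1 and 30 in replicate 2. Of 2202 miRNA genes, 422 had counts in both libraries, 606 in either and 1596 in neither.

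**Figure D2:**
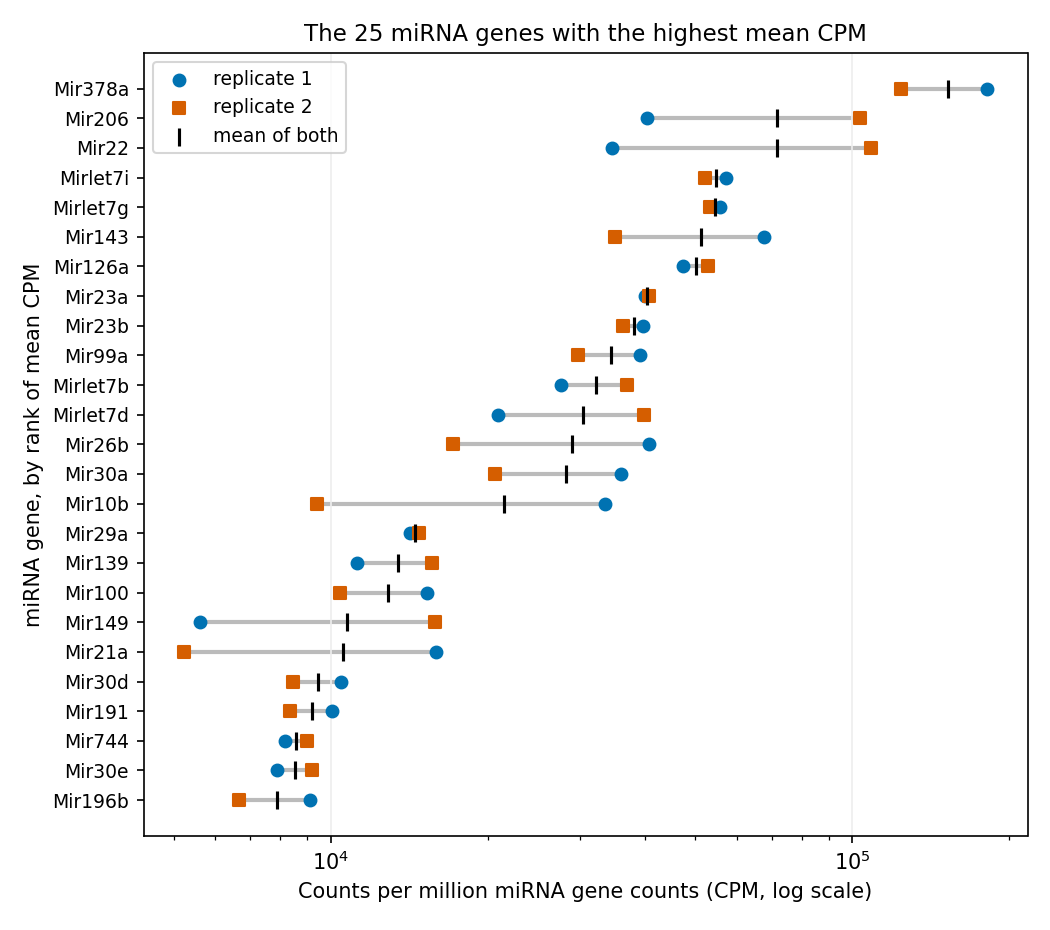
Each row is a miRNA gene, ordered by mean CPM, with a circle for replicate 1, a square for replicate 2 and a bar for their mean on a logarithmic CPM axis. Mir378a leads in both libraries, and the widest gaps among these genes belong to Mir10b, Mir22, Mir21a, Mir149 and Mir206.

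Among the muscle miRNAs, Mir206 had the most gene counts, but the levels of Mir1a and Mir133a are known only as lower bounds. The striated muscle list held 7.21% ± 4.44 of gene counts, 4.07% in replicate 1 (exact Clopper-Pearson interval 4.03 to 4.12) and 10.4% in replicate 2 (10.3 to 10.4). Mir1a-2 and Mir1a-1, whose mature Mir1 is shared by both loci and is a hallmark of striated muscle, stood at 216 ± 76.5 and 23.7 ± 2.39 CPM. Mir133b, which lies beside Mir206 on chromosome 1 (20682769 to 20682887), stood at 48.0 ± 10.7 CPM. Reads that map to both copies enter no gene count, so the levels of Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 are lower bounds. Mir133b shares 21 bases with another hairpin, so its level can be a lower bound as well. The slow fibre list, Mir208b and Mir499, held 0.0569% ± 0.0548 of counts, 0.0181% in replicate 1 and 0.0956% in replicate 2.

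Among the other cell types and tissues, the largest shares belonged to smooth muscle (Mir143 and Mir145a, 5.67% ± 2.65) and endothelium (Mir126a, 5.01% ± 0.402). The leukocyte list held 0.469% ± 0.0345, led by Mir155 at 1776 ± 487 CPM and Mir150 at 1705 ± 59.1 CPM. The fibroblast list held 0.101% ± 0.0530 (0.0633% and 0.138%) and was led by Mir214 at 949 ± 545 CPM. Mir199b shares 28 bases with another hairpin and Mir199a-1 and Mir199a-2 are copies, so this share can be a lower bound. Blood-borne Mir451a stood at 233 ± 42.3 CPM and Mir144 at 39.5 ± 18.2 CPM, which put the erythroid list at 0.0273% ± 0.00605. The Mir486 list, which is not assigned to a cell type here, holds Mir486 and its opposite-strand gene Mir3107 and took 0.355% ± 0.0557. Each shares 22 bases with another hairpin, so this share can be a lower bound. The epithelial list held 0.0306% ± 0.00509, the liver miRNA Mir122 held 0.00527% ± 0.00599 (0.00104% and 0.00951%) and the pancreas list held 0.00413% ± 0.000454. The neural list had 1 count in replicate 1 and 5 in replicate 2. All 6 of its genes are copies of Mir9 or Mir124 that share their mature sequence, so neural RNA cannot be excluded by this list.

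The let-7 list held the largest share of any list, 18.9% ± 1.51. The Mir30 family held 4.77% ± 1.12, the Hox cluster genes 3.80% ± 1.98 (5.20% and 2.40%) and the senescence and fibrosis genes 2.86% ± 0.810. The imprinted Dlk1-Dio3 cluster held 0.461% ± 0.277 (0.265% and 0.657%), the Mir17 to Mir92 cluster 0.319% ± 0.050 and the Sfmbt2 cluster 0.0319% ± 0.000609. Between the libraries, the exact conditional binomial test with Benjamini-Hochberg adjustment over 19 lists gave an adjusted p under 0.05 for all but the neural, pancreas and Sfmbt2 lists. Their adjusted p was 1, 0.555 and 0.763. The leukocyte share, for example, was 1.11 times as high in replicate 2 (interval 1.07 to 1.15, adjusted p = 3.42e-08 by the same exact test), a small difference made measurable by depth.

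Gene levels kept a similar order in both libraries, but single genes such as Mir10b and Mir22 differed by far more than counting error. Across the 305 tested genes, Pearson's r was 0.944 (bootstrap interval 0.926 to 0.958) and Spearman's rho 0.913 (0.878 to 0.936). The SD of the log2 ratio was 1.25, and the median gene was 1.35-fold higher in replicate 2, a log2 ratio of 0.43. The biological coefficient of variation was 0.549 (bootstrap interval 0.487 to 0.589) by edgeR. The more abundant of the tested genes had a median log2 ratio of 0.20 and the less abundant 0.78, with a Spearman correlation of -0.321 between level and ratio across genes. The filter is on raw counts, and replicate 2 held 2.52 times as many, so genes higher in replicate 2 pass it more easily. This selection can add to the shift and to the trend. The median log2 ratio was 0.30 with a mean of at least 100 counts and -0.04 without a filter, where counts of 0 enter at the floor. A gene with 0 counts in replicate 1 then enters at 3.47 CPM, so a few counts in replicate 2 give a ratio toward replicate 1. The -0.04 therefore does not show that the shift is absent without the filter.

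**Figure D3:**
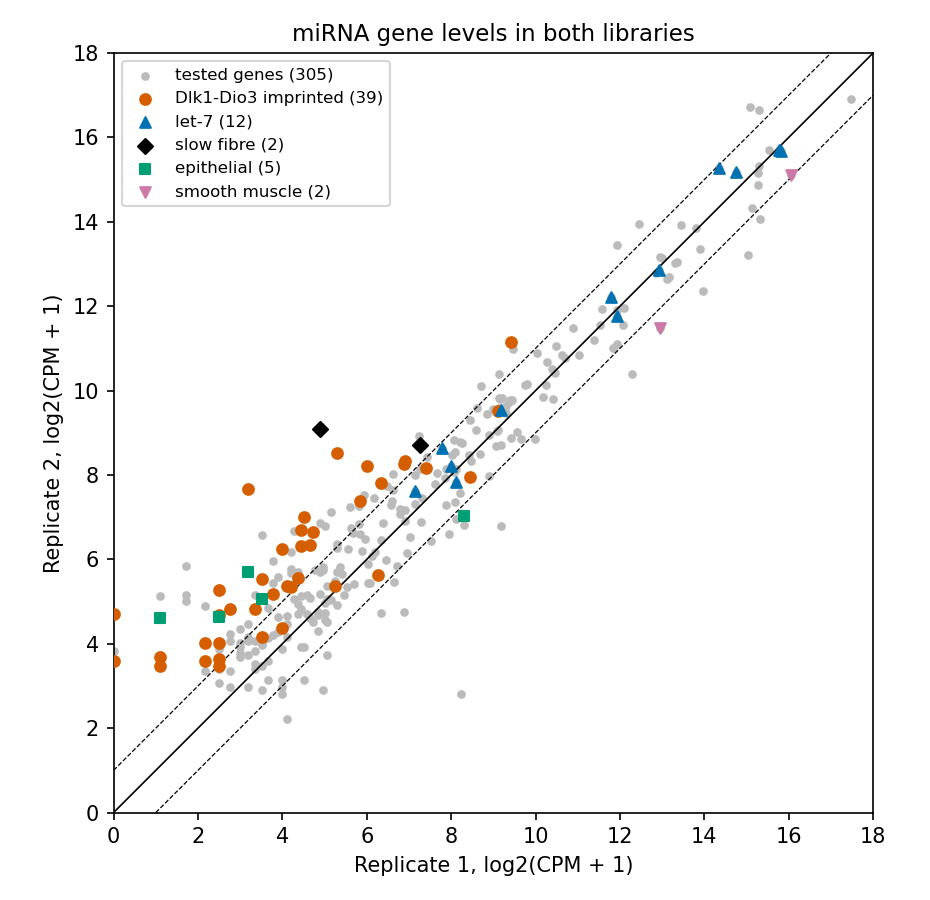
Each point is a tested gene, with log2(CPM + 1) in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis; the solid line marks equality, the dashed lines a 2-fold ratio, and coloured points 5 fixed lists. The 12 let-7 genes lie within 2-fold of equality, both slow fibre genes lie above it, and 29 of the 39 Dlk1-Dio3 genes were called higher in replicate 2.

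Genes called between the replicates lay mostly on the side of replicate 2. Of 305 genes, 103 were called, 82 higher in replicate 2 and 21 higher in replicate 1, so 79.6% were higher in replicate 2. With a mean of at least 100 counts, 37 of 50 called genes were higher in replicate 2 (74%), and without a filter 82 of 105 (78.1%). The split depended on the scaling: TMM, which lowers each ratio by 0.28 on the log2 scale, called 98 genes with 66 higher in replicate 2 (67.3%), and DESeq2 size factors, which lower it by 0.42, called 97 with 58 higher in replicate 2 (59.8%). Of the 25 most abundant genes, 3 were higher in replicate 2, 3 were higher in replicate 1 and 19 were not called. Mir22 was 3.14-fold higher in replicate 2 (exact interval 3.10 to 3.17), Mir149 was 2.82-fold higher (2.74 to 2.91) and Mir206 was 2.56-fold higher (2.53 to 2.59). Mir206 fell below the 2-fold threshold with DESeq2 size factors, at a log2 ratio of 0.94. Mir10b, which lies in an intron of Hoxd3, was 3.56-fold higher in replicate 1 (3.49 to 3.62), Mir21a 3.04-fold (2.97 to 3.12) and Mir26b 2.37-fold (2.34 to 2.41). Mir143 and Mir30a were 1.92-fold and 1.74-fold higher in replicate 1 and passed the threshold only with TMM or DESeq2 size factors.

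The 10 called genes with the largest ratios included 9 that were higher in replicate 2, most of them at low counts. Mir208b had 25 counts in replicate 1 and 1177 in replicate 2, a ratio of 18.7 (interval 12.6 to 29.0), and Mir370 of the Dlk1-Dio3 cluster had 7 and 443, a ratio of 25.2 (12.1 to 62.9). Mir208a, which lies in an intron of the heart myosin gene Myh6, had 1 and 74 counts, a ratio of 29.4 (5.12 to 1177). Mir7b had 2 and 123 counts, Mir219a-2 had 2 and 76, Mir129-2 had 2 and 68, Mir429 had 1 and 51, Gm26117 had 1 and 27 and Mir496a had 1 and 26. Counts of 1 and 2 enter as they are and a count of 0 enters as 3. The order among genes with so few counts, and which of them belong to the 10, is therefore uncertain. Mir26a-1 differed the other way, with 259 counts in replicate 1 and 13 in replicate 2, a ratio of 50.1 toward replicate 1 (28.8 to 95.4). Mir26a-1, Mir219a-2 and Mir129-2 share 25, 22 and 26 bases with another hairpin, so their counts are lower bounds and multimapping can affect their ratios.

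Slow fibre miRNAs were higher in replicate 2. Mir208b, which lies in an intron of the slow myosin gene Myh7 (ENSMUSG00000077928.1, chromosome 14, 54975700 to 54975776, minus strand), stood at 28.9 CPM in replicate 1 and 541 CPM in replicate 2. Mir499, in an intron of Myh7b (ENSMUSG00000076312.1, chromosome 2, 155622880 to 155622958, plus strand), was 2.73-fold higher in replicate 2 (2.27 to 3.30). The median log2 ratio of the list was 2.84, which is 2.40 above the median of all tested genes and above every one of 10000 matched random lists. Both members hold neighbouring ranks by mean CPM, 98 and 99, so both are replaced from nearly the same 20 genes. The 10000 lists therefore repeat few distinct pairs. The striated muscle list, which holds neither Mir208b nor Mir499, was split. With library totals, Mir206 and Mir208a were called higher in replicate 2, while Mir1a-1, Mir1a-2, Mir133a-1 and Mir133b were not called, with Mir133b at a ratio of 1.37 (0.937 to 2.06). Mir1a-2 was called higher in replicate 1 with TMM (log2 ratio -1.02) and with DESeq2 size factors (-1.16). The liver miRNA Mir122 was also higher in replicate 2, at 9 and 207 counts, a ratio of 9.14 (4.72 to 20.3).

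The imprinted Dlk1-Dio3 cluster on chromosome 12 was higher in replicate 2 as a group. Of 39 tested members, 29 were called higher in replicate 2, 0 were called higher in replicate 1 and 10 were not called. DESeq2 size factors called 22 higher in replicate 2 and 1, Mir376c, higher in replicate 1. Chosen after their values were seen, Mir127 (109592846 to 109592915) was 3.29-fold higher in replicate 2 (3.03 to 3.59), Mir433 was 4.68-fold higher (3.55 to 6.29) and Mir770, in an exon of Meg3, was 9.69-fold higher (6.84 to 14.2). Mir411 and Mir379, at ratios of 1.32 (1.19 to 1.46) and 0.710 (0.615 to 0.821), were not called. The median log2 ratio of the list was 1.67, against 0.46 for matched random lists (central 95% 0.13 to 0.78), and lay above all 10000 of them. Several members lie in the same host RNA, such as Mirg, so members of the list are not independent. Random lists draw genes regardless of position, so their band can be too narrow for a cluster. Mir543 and Mir666 had 0 counts in replicate 1 and 55 and 24 in replicate 2, and entered at the floor.

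The tested epithelial miRNAs were also higher in replicate 2, apart from Mir203. The members named here were chosen after their values were seen. Mir200b, Mir200c, Mir205 and Mir429 were called higher in replicate 2, with Mir200c at a ratio of 6.36 (2.99 to 16.2). Mir203 was 2.45-fold higher in replicate 1 (2.07 to 2.91). The list median of 2.37 on the log2 scale lay at percentile 99.6 of matched random lists, although the summed share was lower in replicate 2 (0.0270% against 0.0342%), and Mir203 alone held 275 of 296 and 282 of 588 counts of the list.

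The smooth muscle and Hox medians lay toward replicate 1, though inside the central 95% of matched random lists. Mir145a was 2.76-fold higher in replicate 1 (2.67 to 2.86), and the smooth muscle median was -1.20 on the log2 scale, at percentile 2.99 of matched random lists. Of 6 Hox cluster genes, Mir10b and Mir196a-1 were called higher in replicate 1 and 4 were not called, with a list median of -0.48 (percentile 3.80). Mir196a-1 shares 22 bases with another hairpin, so multimapping can affect its ratio. Of 6 tested leukocyte genes, Mir142 and Mir223 were higher in replicate 1, by 2.56-fold (2.11 to 3.12) and 2.27-fold (1.90 to 2.71). Mir150, Mir155, Mir342 and Mir146 were not called, and the leukocyte median of 0.04 lay at percentile 28.5. In the fibroblast list, Mir214 was 2.37-fold higher in replicate 2 (2.15 to 2.61), a call lost with TMM and with DESeq2 size factors, and Mir199a-2 was higher in replicate 1 at 13 counts in each library. Mir199b was not called, and multimapping can affect the ratio of Mir199a-2, which has a second copy elsewhere.

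No tested let-7, Mir30 or Mir17 to Mir92 gene was called with library totals. None of 12 let-7 genes was called by the exact test with TMM or DESeq2 size factors, although 11 had an unadjusted p under 0.05 with library totals. Of 6 Mir30 genes, Mir30a alone was called with either other scaling. Of 4 tested genes of the Mir17 to Mir92 cluster, TMM called Mir20a and DESeq2 size factors called Mir17 and Mir20a, each higher in replicate 1. Their median log2 ratio of -0.31 lay at percentile 0.21. All of them lie in exons of the host RNA Mir17hg, so they are not independent and this percentile can be too extreme. Among senescence and fibrosis genes, Mir21a was higher in replicate 1, Mir29b-1, 2.14-fold higher in replicate 2 (1.47 to 3.21), was called only with library totals, and Mir29c, 1.79-fold higher in replicate 1, passed the threshold only with TMM and DESeq2 size factors. With library totals, 5 of 7 were not called, among them Mir34a at a ratio of 1.51 (1.35 to 1.69). Mir29b-1 shares 25 bases with another hairpin, so multimapping can affect its ratio. Neither erythroid gene was called. In the Mir486 list, Mir3107 was called higher in replicate 1 and Mir486 was not called. In the Sfmbt2 cluster, 1 of 5 tested genes was called with library totals, Mir467c with 5 and 34 counts, higher in replicate 2. With TMM and with DESeq2 size factors that call was lost and Mir467e, with 106 and 152 counts, was called higher in replicate 1; both genes are named after their values were seen. Adjusted over the list alone with library totals, the number of called genes was the same for every list with at least 2 tested members except the Sfmbt2 cluster, where it was 0.

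**Figure D4:**
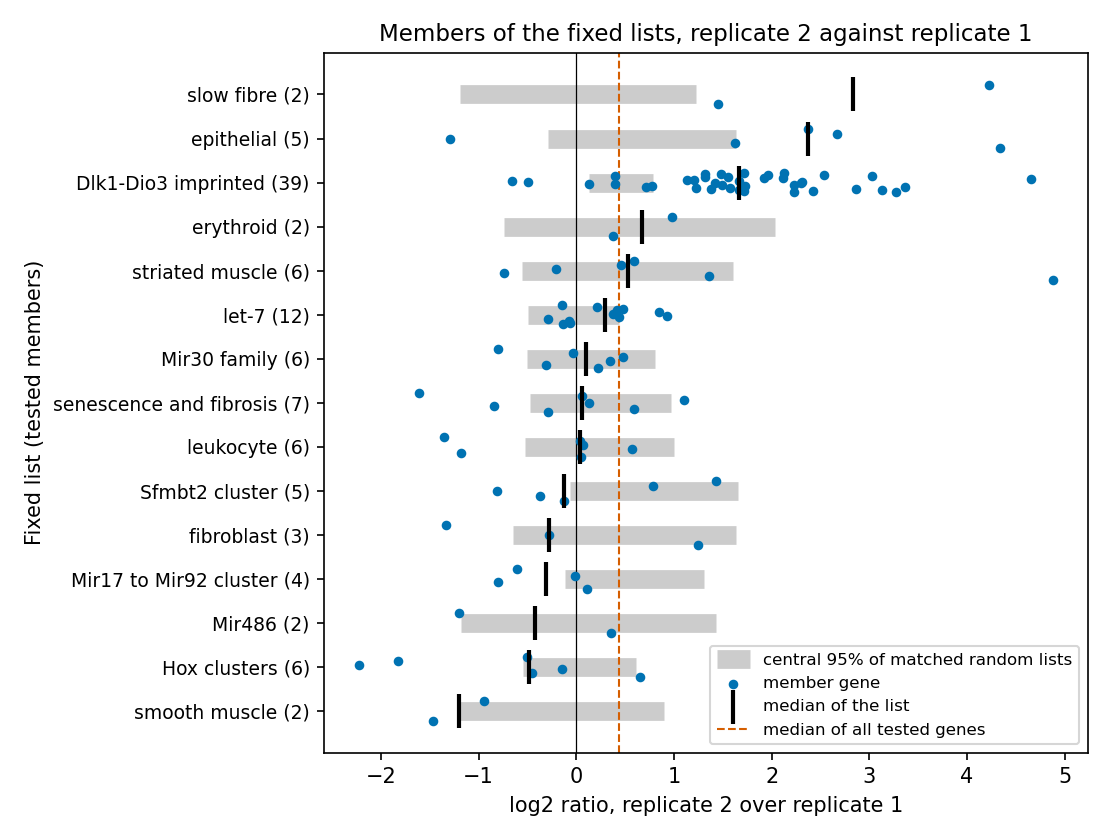
Points are tested members of each fixed list by their log2 ratio of replicate 2 over replicate 1, black bars are list medians, grey bands the central 95% of matched random lists, and the dashed line the median of all tested genes; members with 0 counts in replicate 1 stand at the floor. The medians of the slow fibre (2.84), epithelial (2.37) and Dlk1-Dio3 (1.67) lists lie right of their bands, and those of the Mir17 to Mir92 (-0.31) and Sfmbt2 (-0.13) clusters lie left of theirs. The bands take members of a list as independent, which members of a cluster may not be.

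Genes that lie near each other on a chromosome were counted at unequal levels. Mir206 exceeded Mir133b by 999 to 1 in replicate 1 and 1857 to 1 in replicate 2, a mean log2 ratio of 10.41 ± 0.63, which any multimapping reads of Mir133b would lower. Mir143 exceeded Mir145a by 8.60 and 12.4 to 1, and Mir23b exceeded Mir27b by 5.41 and 5.16 to 1. Mir23b exceeded Mir24-1, which has a second copy elsewhere, by 1323 and 660 to 1. Mir1a-2 exceeded Mir133a-1 by 16.7 and 6.66 to 1, and Mir1a-1 exceeded Mir133a-2 by 11 and 4.36 to 1. Mir144 stood at 0.131 and 0.199 of Mir451a, and Mir199a-2, which has a second copy elsewhere, at 0.0266 and 0.00447 of Mir214. Counts of genes with a second copy are lower bounds, so these ratios carry that limit. The slow fibre genes, which lie on different chromosomes, changed order, with Mir208b at 0.189 of Mir499 in replicate 1 and 1.30 in replicate 2, a mean log2 ratio of -1.01 ± 1.97. No p was taken for these 9 ratios, since 2 libraries allow no two-sided sign-flip p below 0.5.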

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

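Both tests on miRNA families were chosen after the counts had been seen, and the narrower one after the result of the wider one. Multimapping reads, which enter no gene count and no comparison, numbered 5556809 in replicate 1 and 8516459 in replicate 2. They exceeded the counts on miRNA genes by 6.42 to 1 and 3.91 to 1. Antisense counts, also unused, at miRNA genes that face no other miRNA gene summed to 21 in replicate 1 and 52 in replicate 2, beside 644050 and 1726518 sense counts at the same genes. Mir675 held the most of them, with 7 and 12 antisense beside 6 and 13 sense counts, followed in replicate 1 by Mir122 with 5 and in replicate 2 by Mirlet7b with 9. Both are named because they are not 0; as sums over many genes or reads, they would pass the limit of 3 counts of a single gene in any case.

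Mir1a and Mir133a, miRNAs of striated muscle, had few counts in this muscle, at most 216 ± 76.5 CPM for Mir1a-2, while Mir206 stood at 71810 ± 44437 CPM. Reads that map to several copies are left out as multimapping, and a candidate explanation is that this loss is large. Across 17 families with both copy-numbered and other members, the median difference in log2(CPM + 1) was -0.40 and the mean -1.55 (two-sided sign-flip permutation p = 0.146 over 100000 draws). Without other members that face a copy-numbered one and families with a median of 0 on both sides, which cannot show such a loss, the copy-numbered members were lower in 10 of 12 families, with a median of -3.94 and a mean of -3.31 (exact two-sided sign-flip permutation p = 0.00830 over all 4096 flips). The genes in question decide less: Mir133a lay 2.30 below Mir133b but 0.51 above the median of Mir133b and Mir133c, which has 0 counts, and Mir1a has no usable other member. Reads shared by copies of Mir1a and Mir133a enter no gene count, so only the size of that loss stays open. Whether these miRNAs are low in the tissue stays open with it, and the labels name no group that tests a biological explanation.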

How the results depend on the processing

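Alternatives on the medians of lists were added after seeing the data; all others were planned. Pearson's r ranged from 0.929 to 0.958 and Spearman's rho from 0.882 to 0.923; without a count filter r was highest and rho lowest. The coefficient of variation ranged from 0.508 to 0.550. The 103 called genes became 50 with a mean of at least 100 counts, which tests fewer genes, 207 without a ratio threshold, and 91 to 105 otherwise. The slow fibre median stayed between 2.35 and 2.84 and the Dlk1-Dio3 median between 1.25 and 1.67. The 2.35 is a residual after GC correction, which also removes the overall shift of the other genes. TMM and DESeq2 size factors shift a list and its random lists alike and cannot change its rank. Of the 54 other alternative values of list medians, 50 kept their side of the central 95%, these lists among them; the exceptions were smooth muscle after GC correction and 3 of the Sfmbt2 cluster. The unstranded column leaves out reads of opposite miRNA genes as ambiguous, which by construction lowered the shares in percent to 0 for Mir486, 8.69e-05 endothelial and 0.00509 erythroid. By its smaller total it raised those of others to 0.587 leukocyte, 0.0404 epithelial, 0.00537 pancreas, 24.0 let-7, 3.75 senescence and fibrosis, 0.416 Mir17 to Mir92 and 0.0415 Sfmbt2; the top 5 and top 20 genes held 40.2 and 83.8. With Mir378a out of the totals, shares became 0.418 for Mir486, 0.553 leukocyte, 5.91 endothelial, 0.0363 epithelial, 0.00487 pancreas, 22.3 let-7, 0.378 Mir17 to Mir92 and 0.0376 Sfmbt2, as a smaller total gives. Without copy-numbered genes, Mir17 to Mir92, which loses members, became 0.182 and Sfmbt2 0.0325, the top 20 held 84.6 and 26.5 genes held 90%; the neural list then has no member and no value. The log2 ratio of Mir208b to Mir499 ranged from -2.40 without replicate 2 to 0.38 without replicate 1, and the cause was not tested. A single library always lies within 1 SD of a mean of 2, so leaving a library out says little of stability. Agreement, calls and coefficient need both libraries and have no such value. Depth limits the low genes: one with 0 counts in replicate 1 could still lie at up to 3.47 CPM.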

Other observations

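The tests of GC content, scaling and marker genes described here, and the use of matched random lists to judge abundance, were all chosen after the ratios of the genes had been seen. Members of a family did not always differ alike between the libraries. Mir181c and Mir181d, whose symbols carry no copy number, stood at 55.5 and 79.7 CPM in replicate 1 and at 154 and 217 CPM in replicate 2, while Mir181b-2 stood at 1159 and 921 CPM. Mir125a, likewise without a copy number, stood at 3916 and 11167 CPM, while Mir125b-1 and Mir125b-2 stood at 236 and 283 and at 129 and 91.9 CPM. Counts of Mir181b-2, Mir125b-1 and Mir125b-2, which have copies, are lower bounds, so multimapping can affect how these genes differ between the libraries. Genes with a copy number in their symbol, 146 in all, held 2.04% ± 0.0327 of gene counts (n = 2), but the 1128 genes that share at least 18 bases with another hairpin held 45.4% ± 5.17 (49.0% and 41.7%).

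The slow fibre miRNAs Mir208b and Mir499 were higher in replicate 2, with a median log2 ratio of 2.84. GC content and scaling are argued against as the whole cause. After a line on hairpin GC content, fitted on genes outside the list, was removed, the median residual was 2.35. This lay above all matched random lists, which repeat few distinct pairs. The line also removes the overall shift of those genes, so the fall from 2.84 is not the effect of GC content alone. With DESeq2 size factors the median log2 ratio was 2.42. There the exact intervals of the ratios were 9.44 to 21.7 for Mir208b and 1.70 to 2.47 for Mir499. RNA of heart tissue stays open. Its marker Mir208a, a single gene that the striated muscle list also holds, had a ratio of 29.4 (exact interval 5.12 to 1177), but its 74 counts in replicate 2 lay below the 1177 of Mir208b. A different mix of fibres or of neighbouring muscle in the piece of tissue may also account for the pattern, and the labels give no group that tests it.

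The Dlk1-Dio3 list was higher in replicate 2, with a median log2 ratio of 1.67. Random lists matched on mean CPM all lay below 1.67, so the list exceeded genes of like level. This is the comparison that singled out the list, so it is no separate test of a trend with abundance. GC content was argued against by a median residual of 1.35 after a line on hairpin GC content was removed, again above all random lists. Such random lists draw genes regardless of position and do not allow for members of a cluster that move together. RNA of neural tissue cannot be told apart from other causes. The summed counts of 7 single-locus neural miRNAs (Mir137, Mir153, Mir338, Mir383, Mir384, Mir488 and Mir873a) were 1.49-fold higher in replicate 2 (exact interval 1.36 to 1.64). Mir338 held 89.2% of their counts in replicate 1 and could hide a small share, and without it the ratio was 2.42 (1.83 to 3.24), with all 6 remaining genes at a higher CPM in replicate 2. Of these, Mir137 and Mir383 had lower bounds of 1.49 and 1.80. Mir153, Mir384, Mir488 and Mir873a had lower bounds of 0.891, 0.585, 0.496 and 0.468. The less abundant tested genes as a whole had a median log2 ratio of 0.78 toward replicate 2, so the shared direction says little.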
